A study of Arabidopsis thaliana with 3 samples.

How the data were processed

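The series holds 3 DAP-seq libraries of Arabidopsis thaliana: 2 made with recombinant His-tagged GRF5 and root DNA of Col-0 seedlings on 0.2 mM nitrate for 3 days, and 1 input control. Per the labels' protocols, GRF5 was made in Escherichia coli, mixed with sheared genomic DNA, and recovered with an antibody against GRF5 before library preparation. The series design text speaks of a chromatin immunoprecipitation as well and gives its libraries the names that the peak lists carry, whereas titles and protocols of the libraries describe DAP-seq; the latter was followed. If the lists came from chromatin, the peaks would describe occupancy in root tissue. The labels call the GRF5 libraries biological replicates and do not say whether protein or DNA was prepared separately for each, so the spread between them may be technical. A table of values for the input library was not used here.

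Reads were trimmed, aligned and turned into peaks by the authors with Trimmomatic 0.39, Bowtie2 2.4.6 and MACS2 2.2.7.1 on the TAIR10 build, per the submitters' processing notes. Peaks were called in each replicate separately against the shared input, per the file headers and peak names. The caller's settings, read filters and the promoter length of the annotation are not given in the sources used here. The deposited lists give the pileup signal at each summit as a whole number of fragments, with no scaling stated. They give the deposited fold enrichment, a ratio of that pileup to the local background from the input, and the −log10 p and −log10 q at the summit, as written by MACS2 per the file headers. No peak in either list had a q above 0.05. The deposited positions are chromosome, start, end, length in bp and summit, per the file headers; length equalled end minus start, so 1 was added to starts for 1-based coordinates.

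Each list repeats a peak once per annotated gene and region. The 87571 and 82807 entries were collapsed to 28427 and 27133 peaks by chromosome, start and end. Chloroplast and mitochondrial peaks were left out of all comparisons. Region and gene of a peak are the authors' annotation: promoter, coding exon, intron, exon (used in these lists for non-coding genes) or intergenic. Untranslated regions have no class in it.

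Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Peaks were called matched when they overlapped by at least 50% of the shorter one, and each peak was paired with at most 1 partner for the 19008 shared pairs. The strength of a shared peak is the mean of both fold enrichments. The matched share was compared with 100 circular shifts of replicate 2 along each chromosome (one-sided permutation test). Shares carry 95% Wilson intervals, which cover error in counting peaks only. Peaks are not independent units, and all come from a single pair of libraries with a shared input. A region counted for a shared peak when both members of the pair carried it for the same gene. A gene had a promoter peak when a shared pair was annotated to its promoter in both lists. Gene lists were tested by two-sided Fisher's exact tests against all other nuclear protein-coding genes, with 0.5 added to each cell for odds ratios and their intervals. List strength was compared with 10000 random lists of as many genes with a promoter peak (two-sided permutation test). Benjamini-Hochberg adjustment ran over the 10 lists, with a threshold of 0.05. Implied background, used in the closing section, is the pileup plus 1 over the fold enrichment, minus 1, which assumes the caller's usual pseudocount.

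Gene symbols and gene types came from a RefSeq gene table of assembly TAIR10.1, matched on locus tag; 27953 of 27978 gene identifiers in the lists matched and 25 did not. None of its coordinates were used. Lists and rules were fixed before the data were examined. The lists were nitrate transport (17 genes), nitrogen assimilation and ammonium uptake (18), nitrate signalling (33), brassinosteroid synthesis and signalling (25), GRF, GIF and UBP12/13 (14), auxin synthesis, transport and lateral root (23), root and shoot meristem regulators (13), cell cycle (17), and as comparison lists photosynthesis (19) and reference genes of quantitative PCR (9). Genes were named by rule: NRT1.1, NRT2.1, GRF5, BIN2, UBP12 and UBP13 always, the 20 protein-coding genes with the highest mean fold enrichment of a shared promoter peak, and up to 4 members per list with the highest values. The strongest shared peaks in any region, and list members named as present or absent, were added after their values were seen.

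The plan differed from what was run in these points. A window around the transcription start site had been planned for promoters and was replaced by the authors' promoter annotation, since no annotation of the same build was used here. Peak location had been planned by summit. Instead, every region that the authors annotated to a peak was counted, so a peak can fall in several. Tests of the GRF core motif and of short sequences at summits, other promoter windows, and the background of genome shares for peak location needed the genome sequence or gene models and were not run. Alternatives that were run changed the overlap rule (1 bp, 50% of both peaks, summits within 100 bp), the peak threshold (−log10 q of at least 5, the 5000 peaks with the highest −log10 q, at least 3-fold enrichment), the measure of strength (−log10 q), the gene assignment (any region) and the replicate used.

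The methods were tested on simulated data first. A list with 60% of its peaks kept gave a matched share of 61.7% against 65.7% computed from the planted peaks and chance overlap. Of 100 simulated lists of 20 genes among 27444, with 75% of members bound and 1.25 times stronger, the count test called 100 and the strength test 99. Among 900 lists with nothing planted, they called 2.78% and 5.67% before adjustment. The fixed lists had 9 to 33 members, of which 3 to 11 were bound, so the recovery of planted lists does not give the power for them. With location made to depend on peak width alone, the width-stratified odds ratio of the strongest 1% was 1.35 in a first draw and averaged 1.04 over 200 further draws (95% of them from 0.724 to 1.42), where 1 would be no difference.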

Results

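GRF5, a plant transcription factor of the growth-regulating factor family, was profiled by DNA affinity purification sequencing (DAP-seq) in Arabidopsis thaliana. In this assay a purified transcription factor binds genomic DNA in the test tube, the bound fragments are sequenced, and peaks of fragments mark the binding sites. Per the protocols the DNA was purified first, so the peaks describe recovery of naked DNA and not occupancy in root cells. The only control is the input library, with no pull-down lacking GRF5, and the GRF core motif was not tested. Bound is used below for enrichment over input, which does not show that GRF5 itself recovered the DNA. The series design text gives the names carried by these peak lists to a chromatin immunoprecipitation, while titles and protocols give DAP-seq, which is followed here. Recombinant GRF5 was mixed with DNA from roots of wild-type Col-0 seedlings kept on 0.2 mM nitrate for 3 days. The data comprised 2 GRF5 libraries, called replicates 1 and 2, each with a peak list called against the same 1 input library. The series names the nitrate transporters NRT1.1 and NRT2.1 as key targets and the kinase BIN2 and the deubiquitinases UBP12 and UBP13 as partners of GRF5. The questions addressed here were where GRF5 bound, how well the libraries matched, and whether genes of nitrate use, growth and related pathways carried peaks in their promoters. Coordinates are 1-based on TAIR10. Those given for a shared peak are the bounds in replicate 1, and the bounds in replicate 2 can differ. Fold enrichment is the authors' value, the fragment pileup at a peak's summit over the input-based background.

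The strongest GRF5 peak shared by both libraries lay over coding exons and introns of CKL3 (AT4G28880), a casein kinase 1-like gene, on chromosome 4 from 14252685 to 14253982, with a fold enrichment of 12.8 in replicate 1 and 13.1 in replicate 2. The next peak, on chromosome 1 from 20707361 to 20709318, covered coding sequence of AT1G55460 and the promoter of AT1G55450, with 10.6- and 10.8-fold enrichment. In replicate 2 this peak was narrower, from 20707345 to 20707905. A peak over coding sequence of NF-YB3 (AT4G14540), a subunit of the CCAAT-binding NF-Y complex, reached 10.8- and 9.66-fold. PHV (AT1G30490), a class III homeodomain-leucine zipper gene of leaf polarity, carried an 8.86- and 9.87-fold peak over an intron and coding exon. VSP1 (AT5G24780), a vegetative storage protein gene induced by jasmonate, carried an 8.93- and 9.08-fold peak within its coding exons and introns. Not all strong sites were in protein-coding genes: an intergenic site on chromosome 4, from 9847599 to 9848096, had 9.63- and 9.03-fold enrichment, and the pseudogene AT4G06567 lay under a 9.58- and 8.33-fold peak. GRF9 (AT2G45480), another member of GRF5's own family, ranked ninth among shared peaks with 8.34- and 8.64-fold enrichment.

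Such strong sites were few. Replicate 1 had 28427 peaks, 28349 of them on the 5 nuclear chromosomes, and replicate 2 had 27133 peaks, 27054 of them nuclear. The median nuclear peak had a fold enrichment of 1.82 in replicate 1 and 1.84 in replicate 2. A fold enrichment of 3 or more was reached by 366 nuclear peaks of replicate 1 (1.29%) and 349 of replicate 2 (1.29%). Peaks were 423 and 417 bp wide at the median and together covered 14.4 and 13.5 Mb. Total read counts were not used here, so the depth of each library is known only through the median summit pileup, 85 fragments in replicate 1 and 81 in replicate 2.

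Most peaks of each GRF5 library overlapped a peak of the other. Of replicate 1's nuclear peaks, 19283 (68.0%) overlapped a peak of replicate 2 by at least 50% of the shorter peak, and 19362 (71.6%) of replicate 2's peaks overlapped one of replicate 1. When the peaks of replicate 2 were moved along their chromosomes 100 times, the matched share of replicate 1 averaged 14.3% and never exceeded 15.1% (one-sided permutation test, p = 0.0099, the smallest that 100 shifts can give). Matching was nearly complete for the strongest sites: all 284 peaks in the strongest 1% of replicate 1, the CKL3, NF-YB3 and PHV peaks among them, and 270 of 271 in replicate 2 had a partner. In the weakest 25% the matched share was 48.6% (95% Wilson interval 47.4 to 49.7%) in replicate 1 and 54.1% (52.9 to 55.2%) in replicate 2. Overlap did not always mean the same summit: of the 19008 shared pairs, 65.2% had summits within 100 bp of each other. Both lists were called against the same input library, so part of the overlap may be common to them through that input.

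**Figure D1:**
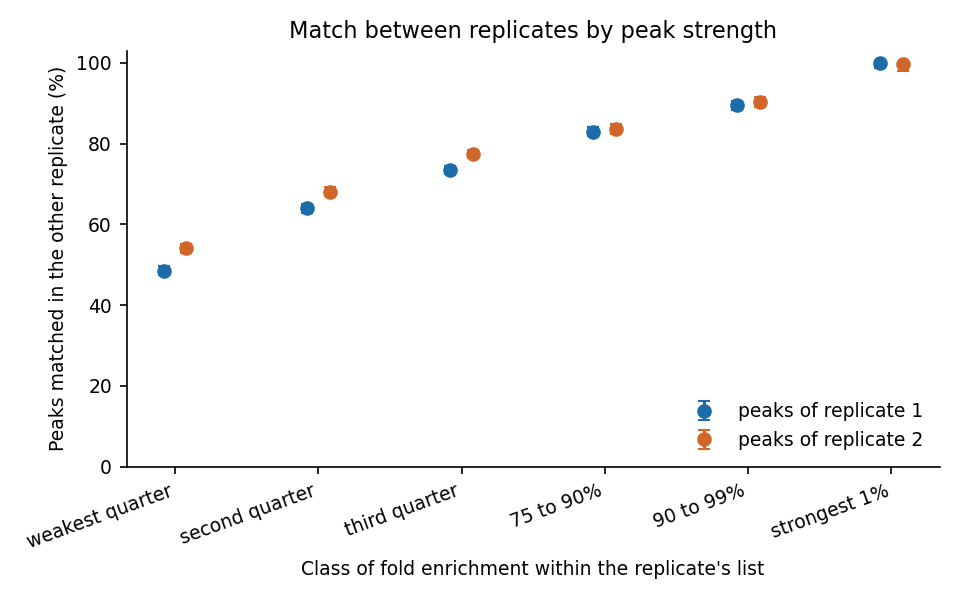
Share of each replicate's nuclear GRF5 peaks (y axis, percent) that had a partner in the other replicate, by class of fold enrichment within the list (x axis). Points are shares and bars 95% Wilson intervals, and the share climbed from 48.6% and 54.1% in the weakest class to 100% and 99.6% in the strongest.

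Across the 19008 one-to-one shared peaks, fold enrichment in the replicates had a Spearman's rho of 0.572, and log2 fold enrichment a Pearson's r of 0.72. These are correlations across peaks of a pair of libraries, and peaks are not independent replicates. Among the 269 shared peaks with at least 3-fold enrichment in both lists, rho was 0.812 and Pearson's r 0.93, and summits lay a median of 6 bp apart. The log2 ratio between replicates had an SD of 0.19 over all shared peaks and 0.15 over these strong ones. Only peaks called in both lists, against the same input, enter these values, so they may understate the spread between the libraries. After scaling for depth, the pileups at these strong peaks varied 0.871 times as much as Poisson counting of fragments would give, and 1.2 times over the 325 shared peaks with a mean of at least 3-fold, a choice made after the data were seen. Since the value moved with the choice of peaks, and amplified fragments are not independent, it does not tell whether the libraries were prepared separately. They were counted as 2 replicates because the labels call them replicates.

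**Figure D2:**
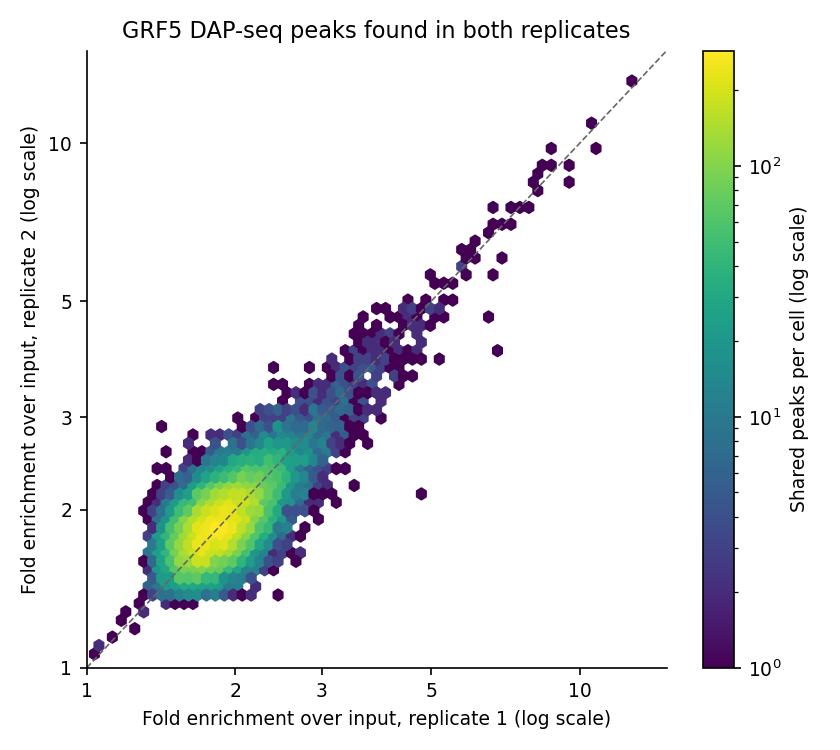
Fold enrichment over input of the 19008 shared nuclear GRF5 peaks in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale). Colour gives the number of peaks per hexagonal cell and the dashed line marks equal values; the points run from a dense cloud around the median of 1.89 to the CKL3 peak at 12.8 and 13.1.

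GRF5 peaks were found both in promoters and in gene bodies. By the authors' annotation, in which a peak can belong to several regions, 10638 of the 19008 shared peaks (56.0%, 95% Wilson interval 55.3 to 56.7%) touched a promoter, as at NRT1.1 and NRT2.1. Coding exons were touched by 51.3% of shared peaks and introns by 47.8%, as in UBP13. Exons of non-coding genes were touched by 7.01%, and 15.7% reached intergenic sequence. Counting coding exons, introns and non-coding exons together, 63.4% of shared peaks lay at least partly in a gene body, and 32.0% lay in a gene body with no promoter annotation. The share of the genome in each class was not used here as a background, so these percentages do not show enrichment of any region.

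Location varied with strength, and not in one direction. The share of shared peaks in gene bodies fell from 68.3% (67.3 to 69.2%) in the weaker 50% of peaks to 49.9% (46.7 to 53.1%) between the 90th and 95th percentiles of fold enrichment. It was 82.7% (76.7 to 87.4%) among the 191 strongest peaks, the top 1%, which includes the peaks over CKL3, NF-YB3, PHV, VSP1 and GRF9. Coding exons showed the same course, with 56.1%, 38.5% and 79.6% in these classes. Promoters were annotated to 55.4%, 56.9% and 44.5% of the peaks in them. The odds of lying in a gene body were 2.79 times higher (95% interval 1.92 to 4.06) for the strongest 1% than for all other shared peaks (two-sided Fisher's exact test, p = 5.75e-09). This contrast was chosen after the values were seen. With the strongest 5% the odds ratio turned to 0.831 (95% interval 0.727 to 0.948, two-sided Fisher's exact test, p = 0.00637). In the single lists it was then 0.681 in replicate 1 and 0.755 in replicate 2. Peaks are not independent replicates, so both p-values describe this pair of libraries only.

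**Figure D3:**
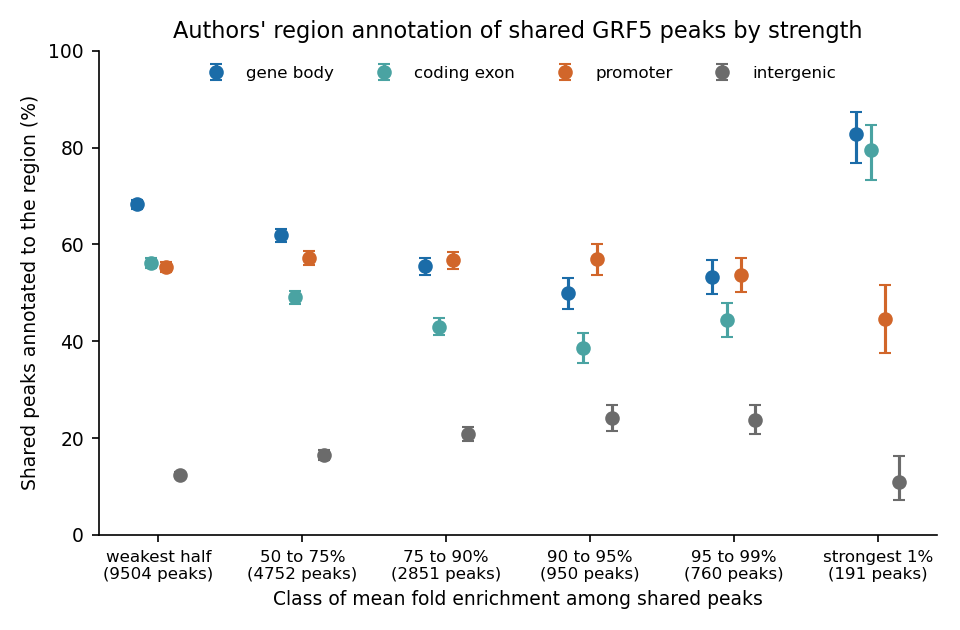
Percent of shared GRF5 peaks (y axis) annotated to gene bodies, coding exons, promoters or intergenic sequence, by class of mean fold enrichment (x axis, with the number of peaks). Points are shares and bars 95% Wilson intervals; a peak can count in several regions, and gene bodies reached 82.7% in the strongest 1% after 49.9% between the 90th and 95th percentiles.

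A shared peak annotated to the promoter was present for 9670 of 27444 nuclear protein-coding genes (35.2%), with a median fold enrichment of 1.90. Of these genes, 145 had a mean enrichment of at least 3-fold. Each peak behind the 20 highest also lay over coding sequence, of the gene itself or of a neighbour, so none of them lay in a promoter alone. Among these 20 were pairs of neighbouring genes under 1 peak. FLA8 (AT2G45470), a fasciclin-like arabinogalactan protein gene, and GRF9 shared the peak on chromosome 2 from 18744776 to 18745598, which also covered GRF9 coding sequence. OFP9 (AT4G04030), of the ovate family of transcriptional repressors, and MEE51 (AT4G04040) shared a peak with 6.91- and 6.13-fold enrichment. AT2G25050 and ENODL14 (AT2G25060), an early nodulin-like protein gene, shared one with 6.64- and 5.65-fold. GDU7 (AT5G38770), of the glutamine dumper family of amino acid export regulators, shared a 7.67- and 7.66-fold peak with AT5G38760. The pair AT1G11630 and AT1G11655 lay on the 8.49- and 8.97-fold peak that covered RBP45B.

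RTH (AT3G51040) had 8.32- and 8.24-fold enrichment, in a peak that also lay over AT3G51050. The promoter of NAC019 (AT1G52890), a stress-responsive NAC transcription factor gene, carried 7.31- and 7.45-fold enrichment on chromosome 1 from 19698237 to 19698810, extending into its coding sequence. XLG1 (AT2G23460), an extra-large G protein gene, had 7.01- and 6.93-fold. RIN1 (AT5G22330) had 6.13- and 6.15-fold. AT4G14530 lay beside NF-YB3 and shared its peak, and AT1G55450 shared that of AT1G55460. The remaining members were AT2G01710, AT1G70630, AT4G28870 and AT3G46760, with mean enrichments from 5.43 to 7.08. None of the 20 belonged to a fixed list except GRF9.

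Both nitrate transporter genes named by the series carried a shared promoter peak, as did 35.2% of all nuclear protein-coding genes. NRT1.1 (AT1G12110), a dual-affinity nitrate transporter and sensor gene, had a promoter peak on chromosome 1 from 4103400 to 4103752 with 2.14-fold enrichment in replicate 1 and 2.09-fold in replicate 2. A second shared peak, from 4107058 to 4107795, lay in an NRT1.1 intron with 2.2- and 2.12-fold. NRT2.1 (AT1G08090), a high-affinity nitrate transporter gene, had a promoter peak from 2521915 to 2522415 with 1.7- and 1.39-fold, higher than those of 2.68% of genes with a promoter peak. This shared peak also reached into intergenic sequence. Replicate 2 alone had a further NRT2.1 promoter peak, from 2523597 to 2523953, with 1.41-fold. The NRT1.1 promoter peak ranked above those of 78.0% of such genes. In replicate 2 the −log10 q of the shared NRT2.1 peak was 1.51.

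The GRF5 gene itself (AT3G13960) had a promoter peak with 2.07- and 2.19-fold enrichment. In replicate 1 it spanned 4606845 to 4609554 on chromosome 3 and ran into coding exons and introns, where replicate 2 had a separate 1.87-fold peak. BIN2 (AT4G18710), a GSK3-like kinase gene of brassinosteroid signalling, had a promoter peak with 1.66- and 1.46-fold on chromosome 4 from 10294323 to 10294665. It was higher than those of 3.4% of genes with a promoter peak, and its −log10 q in replicate 2 was 1.87. A further BIN2 peak over a coding exon and intron had 1.48- and 1.68-fold. UBP12 (AT5G06600) had a promoter peak with 2.00- and 1.84-fold and 3 shared peaks over coding exons and introns, with mean enrichments from 1.86 to 2.08. Its promoter peak also lay over coding sequence and the promoter of the neighbour AT5G06610. UBP13 (AT3G11910) had no promoter peak in either list and carried 3 shared peaks over coding exons and introns, with means from 1.52 to 1.94. Of all nuclear protein-coding genes, 54.4% had a shared peak in some region.

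Among the GRF, GIF and UBP12/13 genes, 9 of 14 (64.3%) had a shared promoter peak, against 35.2% of all other genes. They were GRF2, GRF3, GRF5, GRF6, GRF8, GRF9, GIF1, GIF3 and UBP12; GIF1 and GIF3 encode transcriptional coactivators that bind GRF proteins. GRF3 had 2.33- and 2.25-fold enrichment and GIF1 2.19- and 2.17-fold. The odds ratio was 3.18 (95% interval 1.11 to 9.08), with p = 0.0451 by a two-sided Fisher's exact test and 0.251 after Benjamini-Hochberg adjustment over the 10 lists. The difference therefore did not pass the threshold. It rested on the library used: without replicate 1 the odds ratio was 1.87 (9 of 14 genes, adjusted exact p = 0.483), and without replicate 2 it was 4.95 (12 of 14, adjusted exact p = 0.129). With only peaks of −log10 q of at least 5 the list passed (7 of 14, odds ratio 4.97, adjusted exact p = 0.0424). GRF1, GRF4 and GRF7 had a promoter peak in replicate 1 alone.

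Of the nitrate transport genes, 6 of 17 (35.3%) had a shared promoter peak, with an odds ratio of 1.04 (0.397 to 2.72; two-sided Fisher's exact test, adjusted p = 1). NRT1.2 had 2.26- and 2.38-fold enrichment, NRT1.8 2.12- and 2.25-fold, and NRT2.5 1.99- and 2.16-fold. NRT3.2 was the sixth, beside NRT1.1 and NRT2.1. Replicate 1 alone had promoter peaks at 13 of the 17 genes, NRT3.1, CLCA and SLAH3 included (odds ratio 2.97), and replicate 2 at 6 (0.611). Of all 27444 nuclear protein-coding genes, 13792 had a promoter peak in replicate 1 and 13187 in replicate 2. Nitrogen assimilation and ammonium uptake genes were at 3 of 18 (16.7%; odds ratio 0.415, 0.130 to 1.32, adjusted exact p = 0.344). These were the glutamine synthetase gene GLN1;4 with 2.32- and 1.96-fold, the ammonium transporter gene AMT1;2 with 1.76- and 1.48-fold, and the asparagine synthetase gene ASN2 with 1.62- and 1.60-fold. The nitrate reductase genes NIA1 and NIA2 had no promoter peak in either list. Counting peaks in any region, 10 of the 18 nitrogen assimilation and ammonium uptake genes had a shared peak (55.6%, odds ratio 1.04), against 54.4% of other genes.

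Of the nitrate signalling genes, 11 of 33 (33.3%) had a shared promoter peak, with an odds ratio of 0.939 (0.461 to 1.91; adjusted exact p = 1). Among them were 6 NIN-like protein genes, NLP1, NLP2, NLP5, NLP6, NLP7 and NLP9, which encode transcription factors of the nitrate response. The other NIN-like protein genes listed, NLP3, NLP4 and NLP8, had no shared promoter peak. The values nearest the top of this list were HRS1, a gene of the NIGT1-type transcriptional repressors, with 2.3- and 2.37-fold, TGA4 with 1.7- and 2.17-fold, LBD39 with 1.94- and 1.86-fold, and NLP9 with 1.74- and 1.97-fold. NLP7 had a mean of 1.73.

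Brassinosteroid genes were at 10 of 25 (40%; odds ratio 1.25, 0.569 to 2.73, adjusted exact p = 0.846). BKI1, an inhibitor gene of the receptor BRI1, had 2.2- and 2.03-fold enrichment. The transcription factor genes BZR1 and BEH2 had 1.98- and 1.7-fold and 2.1- and 1.74-fold, and PRE1 had 1.8- and 1.89-fold. Auxin and lateral root genes were at 9 of 23 (39.1%; odds ratio 1.2, 0.531 to 2.73, adjusted exact p = 0.846). The lateral root regulators LBD16 and LBD29 had 2.1- and 2.24-fold and 2.00- and 2.11-fold, the auxin receptor gene TIR1 had 1.93- and 2.21-fold, and ARF19 had 1.84- and 2.15-fold.

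Cell cycle genes had a shared promoter peak in 10 of 17 cases (58.8%; odds ratio 2.57, 1.01 to 6.57, exact p = 0.0714, adjusted 0.251). All 5 D-type cyclin genes listed, CYCD1;1, CYCD2;1, CYCD3;1, CYCD3;2 and CYCD3;3, were among them, CYCD1;1 with 2.35- and 2.26-fold and CYCD2;1 with 1.97- and 2.2-fold. E2FB had 1.81- and 2.27-fold and CYCA2;3 1.68- and 2.22-fold. CYCD3;1, CYCD3;2 and CYCD3;3 had means of 1.76, 1.69 and 1.86. None of KRP1 to KRP4, which encode inhibitors of cyclin-dependent kinases, had a shared promoter peak. However, KRP4 and KRP3 carried shared peaks outside their promoters, with means of 2.53 and 2.24, and KRP1 had a promoter peak in replicate 1 alone. Meristem regulators were at 7 of 13 (53.8%; odds ratio 2.12, 0.742 to 6.07, adjusted exact p = 0.486). The homeobox genes KNAT2, KNAT6 and KNAT1 stood highest, with 2.78- and 2.53-fold, 2.33- and 2.03-fold, and 1.86- and 2.42-fold. SHR, which specifies root endodermis, had 1.77- and 1.97-fold.

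The comparison lists gave values on both sides. Photosynthesis genes were at 5 of 19 (26.3%; odds ratio 0.697, 0.261 to 1.86, adjusted exact p = 0.801). LHCB1.1 and LHCB1.3, adjacent light-harvesting protein genes, shared a peak with 2.45- and 1.97-fold enrichment; RBCS1A had 1.82- and 2.02-fold and LHCA4 1.90- and 1.77-fold. Reference genes used for normalising expression were at 6 of 9 (66.7%; odds ratio 3.41, 0.931 to 12.5, adjusted exact p = 0.251), and the odds ratio was 2.01 without replicate 1 and 1.84 without replicate 2. Of these, the phosphatase subunit gene PP2AA3 had 2.75- and 2.52-fold, EF1A 1.99- and 2.16-fold, TIP41L 1.96- and 2.11-fold and GAPC1 1.89- and 1.75-fold. Of the 10 lists, 0 passed after adjustment and 1, that of the GRF, GIF and UBP12/13 genes, had an unadjusted exact p under 0.05.

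Peak strength within the lists did not separate them from other bound genes. The median enrichment of bound members was highest in nitrate transport, 2.1, at the 93.5th percentile of 10000 random lists of 6 bound genes, and in the GRF, GIF and UBP12/13 list, 2.05, at the 92.7th of lists of its own size. It was lowest in nitrogen assimilation and ammonium uptake, 1.62, at the 1.61st percentile (two-sided permutation p = 0.0324, adjusted 0.324), and in nitrate signalling, 1.76, at the 3.47th (permutation p = 0.0696, adjusted 0.348). Brassinosteroid genes stood at the 8.84th percentile, auxin and lateral root genes at the 23.4th, meristem regulators at the 38.3rd, cell cycle genes at the 48.4th, photosynthesis genes at the 55.1st and reference genes at the 58.5th. None of the 10 passed after adjustment, and 1 had an unadjusted permutation p under 0.05. The nitrogen assimilation value rested on 3 genes. In the single libraries the nitrogen assimilation percentile was 5.18 without replicate 1 and 52.7 without replicate 2, that of nitrate signalling 36.1 and 1.34, and that of nitrate transport 95.2 and 38.5. In the same order, cell cycle genes had 95.3 and 15.1, auxin and lateral root genes 29.8 and 83.2, meristem regulators 62.9 and 44.0, and brassinosteroid genes 14.9 and 8.34.

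**Figure D4:**
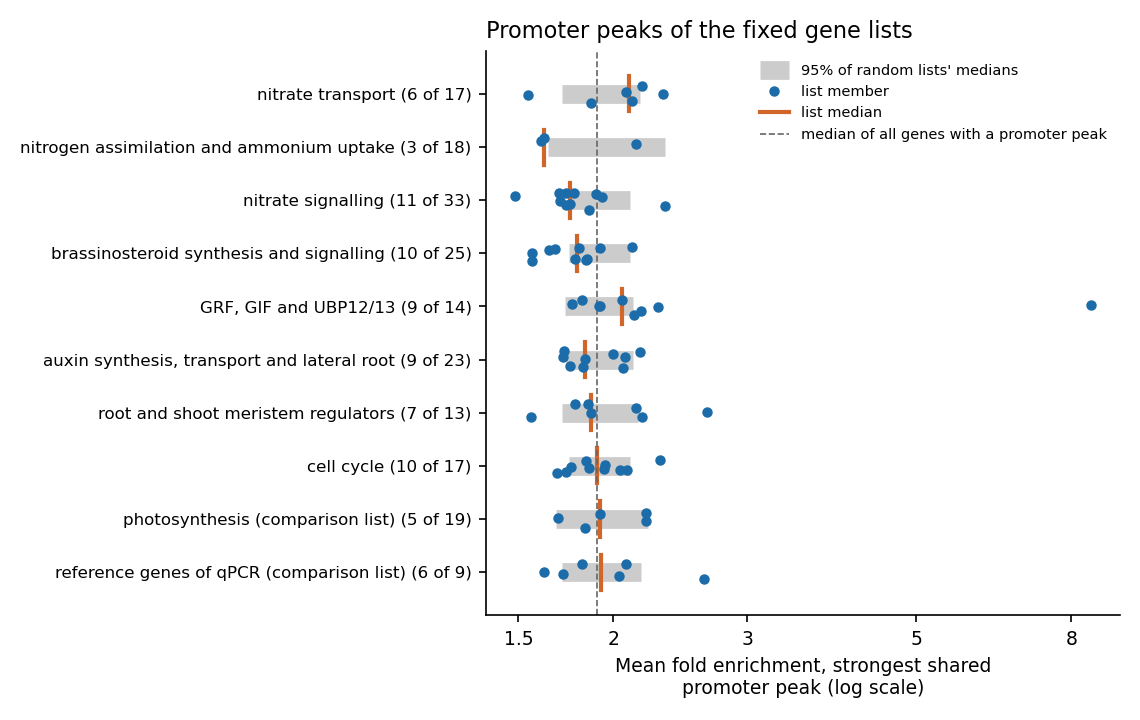
Mean fold enrichment of the strongest shared promoter peak (x axis, log scale) of each bound member of the 10 gene lists (y axis, with bound and total members). Blue points are genes, orange lines list medians, grey bars the middle 95% of the medians of random lists and the dashed line the median of all genes with a promoter peak, 1.90; GRF9 at 8.49 stands apart from the other members.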

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

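No test was run on the peaks described here, and they were set apart because they lie in the organelle genomes, outside all comparisons of the report. The chloroplast genome carried 53 peaks in replicate 1 and 50 in replicate 2, and the mitochondrial genome 25 and 29. Chloroplast peaks had a median summit pileup of 14604 fragments in replicate 1 and 13994 in replicate 2, against 85 and 81 for nuclear peaks, and covered 52.3 and 54.7 kb. Their median fold enrichment was 1.59 and 1.62, and the highest was 2.08 and 2.15. Mitochondrial peaks had median pileups of 782 and 703 and median enrichments of 1.48 and 1.49, with highest values of 2.38 and 2.5.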

How the results depend on the processing

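The contrast of strong peaks in gene bodies, its alternatives, and the comparison of replicate variance with Poisson counting were added after the data were seen; all other settings were fixed before. Not run, for want of a genome sequence or gene models, were the motif and short-sequence tests and the promoter windows. No paired analysis was possible because 1 input library serves both GRF5 libraries and has no list of its own. The matched share of peaks stayed above shifted positions under all 6 alternatives, from 44.8% to 74.0%. Leaving out a library gave 13187 to 13792 genes with a promoter peak, a promoter share of 57.4 to 57.7% and a gene-body odds ratio of 2.17 to 2.39. With −log10 q of at least 5, a list held a mean of 14314 peaks, rho was 0.540 and 4600 genes had a promoter peak; the 5000 peaks with the highest −log10 q (5000 per list) gave 0.644, 1400 genes and a promoter share of 54.6%; at least 3-fold enrichment gave a mean of 357.5 peaks, rho 0.814, 123 genes and 46.1%. Fewer peaks leave fewer genes by construction; the cause of the other shifts was not tested. Reciprocal overlap gave rho 0.599 and a promoter share of 56.8%, summits within 100 bp rho 0.646, and −log10 q as the measure rho 0.551. Any region in place of the promoter gave 14922 genes. Taking the strongest 5% turned the gene-body odds ratio to 0.831, while the other 10 settings kept it above 1.

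For the count of bound genes per list, 13 of 90 alternatives left a list with no bound gene, so that the 0.5 added to each cell sets the odds ratio and its direction says nothing. Of the other 77, 67 kept direction and side of the threshold. The GRF, GIF and UBP12/13 list passed with −log10 q of at least 5 (7 of 14, odds ratio 4.97, adjusted exact p = 0.0424) and under no other alternative, with adjusted exact p from 0.0424 to 0.796. Odds ratios crossed 1 as follows, none past the threshold. Auxin genes gave 0.848 with −log10 q of at least 5, 0.855 with reciprocal overlap, 0.912 in any region and 0.995 to 1.08 in single libraries. Brassinosteroid genes gave 0.304 with −log10 q of at least 5. Nitrate transport gave 0.938 in any region and 0.611 to 2.97 in single libraries, nitrate signalling 0.906 to 1.05 in single libraries, and nitrogen assimilation 1.04 in any region. Among the 13 with no bound gene, values on the other side of 1 were 0.395 for auxin and 0.364 for brassinosteroid genes with the top 5000, and 3.30 for nitrate signalling, 5.98 for nitrogen assimilation and 5.67 for photosynthesis at 3-fold enrichment. For list strength, 63 of 87 alternatives kept the side of the median and none passed. Percentiles that crossed 50 were, for auxin, 62.1 with reciprocal overlap, 66.4 with summits within 100 bp and 29.8 to 83.2 in single libraries; for brassinosteroid genes, 52.8 with −log10 q of at least 5; for cell cycle genes, 50.6 with 1 bp, 64.7 with reciprocal overlap, 51.3 with summits, 61.2 in any region and 15.1 to 95.3 in single libraries; for nitrate transport, 35.8 with the top 5000 and 38.5 to 95.2 in single libraries; for nitrogen assimilation, 58.1 with −log10 q of at least 5 and 5.18 to 52.7 in single libraries. Photosynthesis genes had 33.5 with −log10 q as the measure, 48.5 in any region and 46.3 to 60.8 in single libraries. Reference genes had 45.0 with −log10 q of at least 5, 23.1 with reciprocal overlap and 43.6 with summits. Meristem regulators had 79.2 with the top 5000, 70.4 with −log10 q of at least 5, 88.0 with summits, 89.3 in any region and 44.0 to 62.9 in single libraries. The cause was not tested. Replicate variance over Poisson, 0.871 at peaks of 3-fold in both lists, was 1.2 when they were chosen by mean fold, 1.17 by replicate 1, 1.16 by replicate 2 and 0.665 over all shared peaks. Read depth was not used here, so what it limits was not tested.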

Other observations

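The tests of input background at strong sites and of the input shared by both lists, the draws by width, the contrast of the strongest 1% of peaks and the gene ontology comparison were chosen after the data were seen; the others were set before their results were known. GRF5 peaks also lay over genes that code for no protein. Shared peaks touched exons of 652 long non-coding RNA genes, with a median fold enrichment of 1.90 and a highest value of 4.87, and of 300 pseudogenes, with a median of 1.90 and a highest value of 8.96, that of AT4G06567. Such peaks can also lie over protein-coding genes: the 4.87-fold peak, at AT1G07119, covered coding sequence of AT1G07120 as well. Exons of 8 microRNA genes lay under shared peaks, with a median of 1.88 and a highest value of 2.4. In the nitrate transport list, the strongest peak lay over coding sequence and not in a promoter. SLAH3 (AT5G24030), a slow anion channel gene, carried it on chromosome 5 from 8117730 to 8118769, reaching into intergenic sequence, with 4.76- and 4.67-fold enrichment. Among brassinosteroid genes, BR6OX1 had the highest value in any region, 2.43, and in the nitrogen assimilation list the nitrite reductase gene NIR1 had 2.37, both outside shared promoter peaks.

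When peaks in any region were counted, 14922 protein-coding genes (54.4%) had a shared peak. Photosynthesis genes then stood lowest, with 5 of 19 (26.3%; odds ratio 0.318, 0.119 to 0.849; two-sided Fisher's exact test, p = 0.0192, adjusted 0.192), so no list passed after adjustment. The 500 genes with the highest promoter enrichment were compared with the other promoter-bound genes. Terms came from the authors' gene ontology annotation, in which 9186 promoter-bound genes had terms. Of 781 terms tested by two-sided Fisher's exact tests, 0 passed after Benjamini-Hochberg adjustment and 20 had an unadjusted p under 0.05. The lowest adjusted p was 0.210, for exonucleolytic breakdown of deadenylated mRNA, with 5 of its 12 genes among the 500.

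The strongest 1% of shared peaks lay in gene bodies in 82.7% of cases, against 63.2% of the rest. Strong peaks are wider, 645 bp at the median against 439 bp in the weaker 50%, and a wide peak could touch a gene body more readily, but the odds ratio was 2.33 (95% interval 1.59 to 3.41) when peaks were compared within 10 classes of equal width rank. When location was drawn by width alone 500 times, that odds ratio averaged 1.04 and reached 1.76 at most, so width was not the whole cause. An unusual input background at these sites could raise fold enrichment, but among peaks with a middling implied background the odds ratio was 4.13 (2.07 to 8.28), with 82 strong peaks of 7815. The samples form no groups that differ in biology, so no biological explanation was tested, and sequence content of exons stays open because no genome was used here.

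Replicate peaks coincided far more often than shifted positions. The input library common to both lists may add to this, since implied backgrounds correlated between the lists with a Spearman's rho of 0.857 across shared peaks. A partial correlation of pileups with both backgrounds held fixed, rho 0.558, had been set as the test, but it covers only peaks that already coincide and so decides nothing. If the input alone made peaks coincide, a peak's pileup would not bear on its chance of a match once background and width are equal. Over all nuclear peaks, matched or not, in 500 classes of implied background and width, peaks above the median pileup of their class were matched in 77.0% of cases in replicate 1 and 79.8% in replicate 2, against 59.9% and 64.1% of the others. The odds ratio of a match was 2.48 (95% interval 2.35 to 2.62) and 2.41 (2.27 to 2.56), so the input was not the whole cause. This does not exclude a bias common to both GRF5 libraries, such as copy number or ease of amplification, and no biological explanation was tested.

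Each replicate held peaks with no partner, 9066 in replicate 1 and 7692 in replicate 2. Unmatched peaks had a median fold enrichment of 1.71 and 1.73, against 1.88 and 1.89 for matched ones. What left them without a partner stays open.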
